A study of Arabidopsis thaliana with 8 samples.

How the data were processed

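Gene expression was measured in Arabidopsis thaliana seeds on 8 single-colour Affymetrix arrays, 1 array per sample. Per the labels' protocols, seeds were imbibed for 24 h at 22 °C or 4 °C, total RNA was extracted with a CTAB-based method, and biotin-labelled cRNA was made from it by the array manufacturer's standard protocol. The labels place the samples in 4 groups of 2, made from 2 genotypes and 2 imbibition temperatures. No label says that the replicates came from separately grown or separately imbibed seed lots, so p-values measure the spread between these samples, which may be technical.

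The deposited values are a probe-set intensity for each array on a linear scale. The submitters' processing notes name GCOS, the array manufacturer's software, and its version, the summary algorithm and the scaling target are not given in the sources used here. The table held 22746 probe sets with values on all 8 arrays, and no column was left unused. It held 0 rows of the manufacturer's control probe sets and no detection calls, so no control-based check of RNA quality was made. The intensities were not on a common scale to within the limit set before the data were examined. The mean with 2% trimmed from each tail lay up to 9.71% from the median of the 8 arrays, against a tolerance of 5%, so the arrays were quantile normalized. Quantile normalization gives every array the same distribution, so a shift of most transcripts in one direction would not be visible in the main values.

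Values were analysed as log2(intensity + 1). The pseudocount of 1 came from the 10th percentile of all values, which was 0.80, rounded and kept at 1 or more. A fold change is therefore on the log2(intensity + 1) scale and understates the change of dim probe sets. Probe sets with a mean log2 value below the 40th percentile were left out. That level was 2.86, an intensity of 6.26, and 13648 probe sets were tested. The number of arrays limits the precision: the median half-width of a 95% interval was 0.52 log2 units for a difference between groups and 0.74 for the interaction.

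The test was limma (version 3.58.1, in R 4.3.3), with a coefficient for each group fitted to all 8 arrays, 4 residual degrees of freedom, and empirical Bayes moderation with an intensity trend, which added 9.93 prior degrees of freedom. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. There were 5 contrasts. They were 35S-GSH1 against Col-0 at each temperature, 4 °C against 22 °C in each genotype, and the interaction, which is the temperature difference in 35S-GSH1 minus that in Col-0. Gene lists with at least 5 tested genes were tested with camera from limma at a preset inter-gene correlation of 0.01, with adjustment over all lists and contrasts. Camera with an estimated correlation and fry were run beside it.

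Gene names came from a table that pairs the array's probe sets with genes. In it 13513 probe sets had 1 gene, 503 had several and 8730 had no listed gene, and only those with 1 gene were named. Of the named probe sets, 13436 were matched to the RefSeq gene table of assembly TAIR10.1 and 77 were not. That table was used for names and for whether a gene lies in the nucleus, plastid or mitochondrion, and no coordinates are given, since no source names a genome build. After the filter 7530 named genes were left, each represented by its probe set with the highest mean. No probe set was paired with GSH1 itself, so the level of the overexpressed gene, which would check the genotype labels, was not analysed here, and the genotype of each array rests on its label. Before the data were examined, 21 lists holding 383 genes were fixed, of which 52 genes could be tested. Only 4 lists reached 5 tested genes, namely heat shock proteins, cold-regulated genes, late embryogenesis abundant proteins, and thioredoxins and glutaredoxins, which made 20 list tests. Planned lists of ribosomal proteins and proteasome subunits were left out because the tables used here give no descriptions.

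The genes to name were set by a rule written before the data were examined. For each genotype and temperature contrast these were the 10 largest changes in each direction past the threshold with both replicates of one group beyond both of the other, and up to 4 members per gene list with the smallest adjusted p. Most of the 10 largest changes were unnamed probe sets. The rule was therefore applied among the probe sets with 1 gene, a choice made after the data were seen. The alternative settings were another pseudocount, the deposited scale, centring each array on its median, other filters, moderation without the trend or with robust priors, a fit on the 4 arrays of a comparison alone, the replicate number as a block, other thresholds, and leaving out each array in turn. When 1 array was left out, the lone array of its group was assumed to vary like the other groups.

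The procedure was tested on simulated data for the 13648 probe sets, with 200 of them changed. Means were the observed ones, and variances were drawn from the distribution that limma fitted to the data. The noise was normal and independent between probe sets and arrays. A small list of other genes was also shifted, by less than 2-fold, for the list test. Normalization and filtering were not repeated on the simulated values. Correlation between genes and a part shared by arrays of the same number were not simulated, so the recovered shares may be too high for these data. The shares also depend on how many probe sets change. In the data 953 passed for temperature in Col-0 and 0 for genotype at 22 °C. The 200 changed here may therefore be too few for the first and too many for the second. For the genotype comparison at 22 °C it recovered 34% of the 2-fold changes and 83% of the 4-fold changes. For temperature in Col-0 these shares were 23% and 86%, and for the interaction 5% and 67%. Among the unchanged probe sets it called 5, 8 and 3 in the same order. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.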

Results

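Transcript levels were compared in imbibed Arabidopsis seeds that differed in genotype and in the temperature of imbibition. Col-0 is the wild type, and 35S-GSH1 is a line in the same background that overexpresses GSH1, per the labels. GSH1 encodes glutamate-cysteine ligase, the enzyme of the first step of glutathione synthesis, and 35S is a viral promoter used for strong expression in plants. Seeds of each genotype were imbibed for 24 h at 22 °C or at 4 °C, and the labels describe the 4 °C seeds as imbibed with vernalization. Each of the 4 groups held 2 arrays. The median deposited intensity per array ran from 12.3 to 16.2, and the 100 brightest probe sets took 19.0% to 22.2% of the summed intensity. Across the 13648 probe sets tested, replicate arrays of a group correlated with Pearson's r of 0.962 to 0.972. Arrays of the other genotype at the same temperature correlated as closely (0.961 to 0.980), while arrays of different temperature gave 0.940 to 0.959.

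The first comparison asked which transcripts differed between 35S-GSH1 and Col-0 seeds imbibed at 22 °C. No gene passed the test, and values of some tested genes of glutathione and sulfur metabolism are given here without a call. Tested were 2 of the 16 genes fixed for glutathione synthesis and turnover and 4 of 37 glutathione transferases. For sulfate uptake and assimilation it was 3 of 28. The cytosolic and peroxisomal glutathione reductase GR1 (AT3G24170) had a log2 difference of 0.22 (SE 0.19, n = 2 per group, limma adjusted p = 0.897), and the organellar glutathione reductase GR (AT3G54660) one of 0.045 (SE 0.16), which was -0.021 without Col-0 22 °C replicate 2. Of the 4 glutathione transferases tested, GSTU22 had a log2 difference of 0.58 and GSTU28 one of -0.64, each with a limma adjusted p above the threshold (0.862 and 0.853). Sulfite reductase SIR, the enzyme that makes sulfide in sulfate assimilation, had 0.41 (SE 0.21, limma adjusted p = 0.862). The gibberellin receptor GID1A had 0.37 (limma adjusted p = 0.853), the small heat shock protein ATHSP22.0 had 0.44 (limma adjusted p = 0.844), and AT12CYS had -1.22 (SE 0.52, limma adjusted p = 0.853).

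With limma, 0 of 13648 probe sets passed the threshold at 22 °C, and the smallest adjusted p was 0.176. At an unadjusted p under 0.05 there were 779, where 682 would fall by chance. None of the 4 testable gene lists passed camera in this contrast: heat shock proteins, late embryogenesis abundant proteins, and thioredoxins and glutaredoxins each had an adjusted p of 0.410, and cold-regulated genes 0.900. None of the 52 tested members of the fixed lists passed, either over all probe sets or adjusted over the list alone, and 3 lists (abscisic acid, endosperm and seed coat) had no tested member. The count went from 0 to 1 without Col-0 22 °C replicate 1 and likewise without Col-0 22 °C replicate 2. On simulated data with independent noise the same test recovered 34% of the 2-fold and 83% of the 4-fold differences in this comparison, shares that may be too high for these data.

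At 4 °C, the seeds of the genotypes again showed no single transcript past the threshold, while the heat shock proteins as a list stood higher in 35S-GSH1 by 1 of 3 list tests. The 5 heat shock proteins tested had a median log2 difference of 0.21 and all lay above 0. The cytosolic small heat shock proteins HSP17.6B (AT2G29500) and HSP17.6C (AT1G53540) had differences of 0.35 (SE 0.15) and 0.30 (SE 0.15), each with a limma adjusted p of 1. Camera gave the list an adjusted p of 0.0104, but the adjusted p was 0.226 with an estimated correlation and 0.0707 with fry, and without 35S-GSH1 4 °C replicate 1 it was 0.171. The largest difference among the fixed lists was that of ATMDAR2 (AT5G03630), a monodehydroascorbate reductase of the antioxidant list. It stood at -2.13 (SE 0.57), with a limma adjusted p of 1 over all probe sets and 0.00471 adjusted over the list alone, in a list with 2 tested members. The ATP sulfurylase APS4 had -0.74 (SE 0.36), the cysteine protease CP1 -0.82 (SE 0.33) and the clock gene GI -0.49 (SE 0.20). Adjusted over the list alone, CP1 (limma adjusted p = 0.0271) and GI (limma adjusted p = 0.0268 in the clock list) also passed, each as the only tested member of that list. GI is in the vernalization and flowering time list too, where 0 of 3 tested members passed when adjusted over the list alone. GR1 had -0.031 (SE 0.19), which was 0.094 without Col-0 4 °C replicate 2 and 0.0052 without 35S-GSH1 4 °C replicate 2.

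With limma, 0 of 13648 probe sets passed the threshold for genotype at 4 °C, and 439 had an unadjusted p under 0.05, where 682 would fall by chance. Camera gave adjusted p-values of 0.504 for late embryogenesis abundant proteins, 0.730 for thioredoxins and glutaredoxins and 0.933 for cold-regulated genes. Without Col-0 4 °C replicate 2 the count was 1. The overlap of genotype differences between the temperatures was 0 probe sets, since neither contrast had any. Across all probe sets, which are not independent replicates, the log2 differences at 22 °C and 4 °C correlated with a Pearson's r of 0.07 and a Spearman's rho of 0.07.

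The next comparison asked which transcripts differed between wild-type seeds imbibed at 4 °C and at 22 °C. All samples were taken at 24 h, with none from before imbibition or from another time. A rise or a fall therefore means a higher or lower level at 4 °C than at 22 °C. The stage that the seeds had reached at each temperature was not measured, so it cannot be told apart from a response to the temperature. STZ (AT1G27730), a zinc-finger transcriptional repressor also known as ZAT10, rose by a log2 fold change of 2.12 (4.35-fold, SE 0.23, n = 2 per group, limma adjusted p = 0.000156). The late embryogenesis abundant gene LEA25 (AT2G42560) rose by 1.98 (SE 0.15, limma adjusted p = 4.09e-06), and GI (AT1G22770), a clock and flowering-time gene, by 1.43 (SE 0.20, limma adjusted p = 0.000882). The mitochondrial small heat shock protein HSP23.5 (AT5G51440) fell by 2.85 (SE 0.18, limma adjusted p = 4.96e-07). AT4G33560 fell from a mean log2 value of 5.58 at 22 °C to 0.55 at 4 °C, a log2 fold change of -5.03 (SE 0.65, limma adjusted p = 0.000519), whose size and rank are uncertain since the value at 4 °C lies below the filter level of 2.86.

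In Col-0, limma placed 953 of 13648 probe sets past the threshold, 502 higher and 451 lower at 4 °C, and 468 of them had a gene name. At least 2-fold changes were found in 196 higher and 212 lower probe sets. The other named genes with the largest rises were AT3G06750 (2.78), AT4G28703 (2.75), AT5G04500 (2.73), AT1G18740 (2.64), the leucine-rich repeat receptor kinase gene AT5G58300 (2.63), AT3G19680 (2.49), AT3G28330 (2.28) and AT5G11070 (1.95). The other named genes with the largest drops were AT5G10040 (-3.86), AT1G10050 (-3.28), AT3G15770 (-3.21), AT3G48140 (-3.14), AT5G66985 (-3.11), AT1G59660 (-3.05), ZCF37 (-3.01) and AT5G19120 (-2.97). Their limma adjusted p-values ran from 4.09e-06 for AT1G18740 to 0.0430 for AT3G28330. Leaving out 1 array ended the calls of AT3G06750, AT4G28703, AT5G58300, AT3G28330 and AT5G11070, with adjusted p-values of up to 0.0769 (without Col-0 4 °C replicate 2), 0.142 (without Col-0 4 °C replicate 1), 0.136 (without Col-0 4 °C replicate 1), 0.217 (without Col-0 22 °C replicate 1) and 0.166 (without Col-0 4 °C replicate 1). The group with the lower level had a mean below the filter level of 2.86 for 4 of the 10 named genes that rose and 5 of the 10 that fell, so the size and the rank of these changes depend on values near the bottom of the scale. The largest changes of all were in unnamed probe sets, 264661_at with a log2 fold change of 3.66 and 263096_at with -5.35.

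By gene list in Col-0, of the 5 heat shock proteins tested HSP23.5 and HSP17.6B (log2 fold change -0.71, SE 0.15, limma adjusted p = 0.0124) fell and 3 did not pass; adjusted over the list alone 3 fell, the other one being HSP17.6C (-0.43). Camera gave the list an adjusted p of 0.0104 and fry one of 0.00333, while the adjusted p was 0.226 with an estimated correlation. The call of HSP17.6B was lost without Col-0 22 °C replicate 1 (adjusted p = 0.0723) and without Col-0 4 °C replicate 1 (adjusted p = 0.115). Among the 5 cold-regulated genes tested STZ rose, which was also the only one of the 4 tested genes of the oxidative and mitochondrial stress list to pass, and 4 did not pass. COR27, a cold-regulated gene that is also part of the clock, had 0.63 (limma adjusted p = 0.0595) and the lipocalin TIL -0.43 (limma adjusted p = 0.0760); adjusted over the list alone 2 rose and 1 fell. Camera gave this list an adjusted p of 0.214. Of the 10 late embryogenesis abundant genes LEA25 rose and 9 did not pass, and adjusted over the list alone LEA48 (0.80) joined it, with a camera adjusted p of 0.225. Thioredoxins and glutaredoxins had 0 of 5 members past the threshold, a median of 0.089 against a mean of -0.13, and a camera adjusted p of 0.900. In the lists too small for a list test, the stromal and mitochondrial ascorbate peroxidase SAPX fell by 0.90 (limma adjusted p = 0.0465), a call that was lost without any 1 of 7 arrays, with an adjusted p of up to 0.336 without Col-0 4 °C replicate 1. GR1 had -0.65 (limma adjusted p = 0.0506), GSTU22 -0.91 (limma adjusted p = 0.0703), SIR 0.61 (limma adjusted p = 0.0959) and the light-harvesting gene LHCB4.1 0.53 (limma adjusted p = 0.0735); each of these 4 genes passed when adjusted over the list alone.

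The split of the Col-0 calls depended on the scaling. On the deposited scale 642 were higher and 351 lower (64.7% higher, against 52.7% in the main values), and with arrays centred on their medians 389 were higher and 618 lower (38.6%). The count was 153 without the intensity trend in the moderation, 427 without Col-0 22 °C replicate 1, 435 without Col-0 4 °C replicate 1 and 512 without Col-0 4 °C replicate 2.

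**Figure D1:**
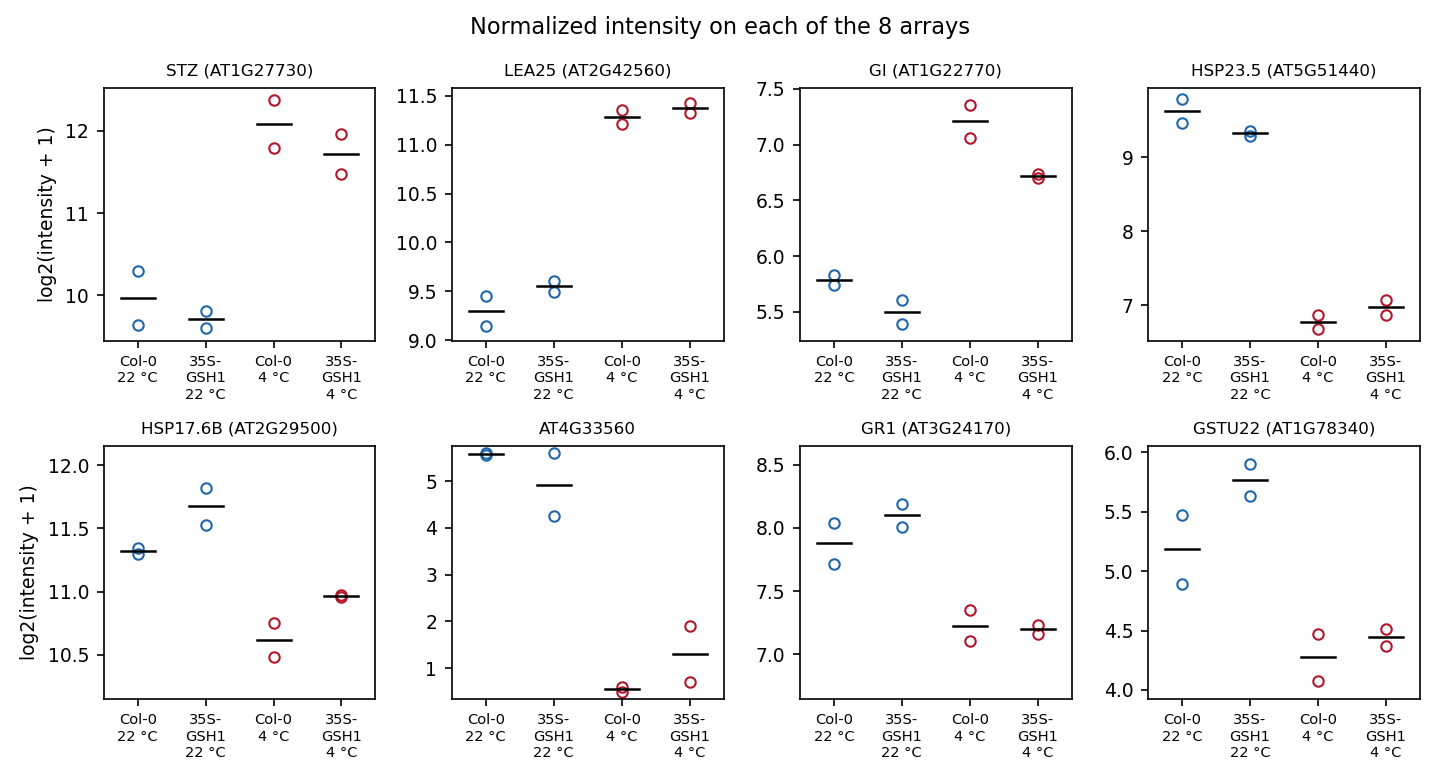
Normalized log2(intensity + 1) of 8 named genes on each array, with 1 circle per array, 2 arrays per group and a horizontal line at the group mean (blue, 22 °C; red, 4 °C). STZ, LEA25 and GI lie higher on all 4 arrays at 4 °C than on any array at 22 °C, and HSP23.5, HSP17.6B, AT4G33560, GR1 and GSTU22 lie lower, although GR1 and GSTU22 passed the threshold in 35S-GSH1 but not in Col-0; the vertical axes do not start at 0 and differ between genes.

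The same temperature comparison was made in 35S-GSH1 seeds. STZ rose by a log2 fold change of 2.01 (SE 0.23, n = 2 per group, limma adjusted p = 0.000252), LEA25 by 1.83 (SE 0.15, limma adjusted p = 1.43e-05) and GI by 1.22 (SE 0.20, limma adjusted p = 0.00281). HSP23.5 fell by 2.36 (SE 0.18, limma adjusted p = 4.07e-06). Single members of 3 small fixed lists also fell at 4 °C: GR1, 1 of 2 glutathione genes tested, by 0.90 (SE 0.19, limma adjusted p = 0.0116), GSTU22, 1 of 4 glutathione transferases, by 1.33 (SE 0.28, limma adjusted p = 0.0138) and ATMDAR2, 1 of 2 antioxidant genes, by 2.12 (SE 0.57, limma adjusted p = 0.0458). AT3G25290 fell by 4.03 (SE 0.43, limma adjusted p = 0.000131), and AT5G57250 rose by 3.28 (SE 0.71, limma adjusted p = 0.0164). Some of these calls depended on single arrays: without 35S-GSH1 22 °C replicate 1 the adjusted p was 0.112 for GR1, 0.130 for GSTU22, 0.314 for ATMDAR2 and 0.132 for AT5G57250. The call of GR1 was also lost without 35S-GSH1 4 °C replicate 1 (0.0600) and replicate 2 (0.0926), that of GSTU22 without any 1 of the 4 35S-GSH1 arrays, that of AT5G57250 without either 35S-GSH1 4 °C array, and that of ATMDAR2 without any 1 of 7 arrays.

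In 35S-GSH1, limma placed 762 of 13648 probe sets past the threshold, 382 higher and 380 lower at 4 °C, and 358 of them had a gene name. At least 2-fold changes were found in 177 higher and 196 lower probe sets. The other named genes with the largest rises were AT2G41770 (3.04), AT5G11070 (2.73), AT3G19680 (2.57), AT4G31875 (2.41), AT3G06750 (2.29), AT1G78410 (2.12), the glucosyltransferase gene UGT85A7 (4.01-fold) and AT1G18740 (1.94). The other named genes with the largest drops were AT4G33560 (-3.61), AT3G19360 (-3.21), AT2G14255 (-2.97), AT1G77030 (-2.90), AT4G39670 (-2.87), AT5G19120 (-2.77), AT4G22560 (-2.76), AT3G48140 (-2.67) and ZCF37 (-2.65). Their limma adjusted p-values ran from 3.6e-05 for AT3G19680 to 0.0462 for AT2G14255. Leaving out 1 array ended the calls of AT3G06750, AT1G78410, UGT85A7, AT2G14255, AT1G77030, AT4G22560 and ZCF37. The highest adjusted p was 0.134 for AT1G78410, 0.223 for UGT85A7 and 0.0675 for ZCF37 without 35S-GSH1 22 °C replicate 1, and 0.156 for AT3G06750 and 0.0853 for AT1G77030 without 35S-GSH1 22 °C replicate 2. Without 35S-GSH1 4 °C replicate 1 it was 0.182 for AT2G14255 and 0.0690 for AT4G22560. The group with the lower level had a mean below the filter level of 2.86 for 6 of the 10 named genes that rose and 7 of the 10 that fell, AT4G33560 and AT3G25290 among them, so the size and the rank of these changes are uncertain. The unnamed probe sets with the largest changes were 245757_at with a log2 fold change of 3.83 and 263096_at with -5.52.

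By gene list in 35S-GSH1, HSP23.5 and HSP17.6B (-0.71, SE 0.15, limma adjusted p = 0.0143) fell among the 5 heat shock proteins and 3 did not pass, and the count adjusted over the list alone was the same 2. Camera gave this list an adjusted p of 0.0127, fry gave 0.00333, and the adjusted p was 0.226 with an estimated correlation. The camera call of the list was lost without 35S-GSH1 22 °C replicate 2. The call of HSP17.6B was lost without that array (log2 fold change -0.55). It was also lost without 35S-GSH1 4 °C replicate 1 (-0.71) and without 35S-GSH1 4 °C replicate 2 (-0.70). Among the 5 cold-regulated genes STZ rose, TIL fell by 0.51 (SE 0.14, limma adjusted p = 0.0404) and 3 did not pass; COR28 had 0.59 (limma adjusted p = 0.219) and COR27 had 0.45 (limma adjusted p = 0.202). Adjusted over the list alone 3 cold-regulated genes rose and 1 fell, with a camera adjusted p of 0.0890. LEA25 was the only one of 10 late embryogenesis abundant genes to pass, with a camera adjusted p of 0.231, and 0 of 5 thioredoxins and glutaredoxins passed, with a camera adjusted p of 0.730. In the small lists CP1 fell by 1.26 (SE 0.33, limma adjusted p = 0.0399), a call lost without any 1 of the 4 35S-GSH1 arrays (log2 fold change -1.13 without 22 °C replicate 1). The oleosin OLEO3 had 0.40 (limma adjusted p = 0.244) and LHCB4.1 had 0.53 (limma adjusted p = 0.0779), and both passed when adjusted over the list alone. OLEO3 was the only tested member of its list, so that adjustment left its p unchanged. The call of TIL was lost without any 1 of 6 arrays, with an adjusted p of up to 0.190 without 35S-GSH1 4 °C replicate 1.

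On the deposited scale the 35S-GSH1 calls were 609 higher and 281 lower (68.4% higher, against 50.1% in the main values), with a median shift of all probe sets of 0.12 log2 units, and with arrays centred on their medians 334 were higher and 464 lower (41.9%). The count was 117 without the intensity trend, and 257, 357, 316 and 277 without 35S-GSH1 22 °C replicate 1, 22 °C replicate 2, 4 °C replicate 1 and 4 °C replicate 2.

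The temperature differences of the genotypes were then set against each other. STZ, LEA25, GI, AT3G19680, AT3G06750, AT5G11070 and AT1G18740 rose in both genotypes, and HSP23.5, HSP17.6B, AT4G33560, AT3G48140, AT5G19120 and ZCF37 fell in both. In all, 232 probe sets were higher at 4 °C in both genotypes and 237 lower in both, where independent lists of the same lengths would share 14.1 and 12.6, and 0 changed in opposite directions. The contrasts share no array, but they use the same variance estimate for each probe set. The numbers expected for independent lists may therefore be too low. A further 484 probe sets passed in Col-0 alone and 293 in 35S-GSH1 alone, which by itself does not show a difference between genotypes. Of the 1246 probe sets past the threshold in either genotype, 97.9% had the same sign in both. Across all 13648 probe sets the log2 fold changes correlated with a Pearson's r of 0.57 and a Spearman's rho of 0.53, with probe sets not being independent replicates.

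The difference itself was tested as the interaction of genotype and temperature. ATMDAR2 fell at 4 °C in 35S-GSH1, and its interaction was -2.67 (SE 0.81) with a limma adjusted p of 0.9996 over all probe sets and 0.0109 adjusted over the list alone. With limma, 0 of 13648 probe sets passed, and 453 had an unadjusted p under 0.05, where 682 would fall by chance. Camera gave the 4 testable lists adjusted p-values between 0.410 for heat shock proteins and 0.900 for cold-regulated genes, whose median (-0.084) and mean (0.044) differed in sign, as did those of thioredoxins and glutaredoxins (0.012 and -0.028). The number of probe sets shared by the temperature contrasts was 469, and it was 70 without the intensity trend; it was 267 and 287 without Col-0 22 °C replicate 1 and Col-0 4 °C replicate 1, and 202, 235, 240 and 205 without 35S-GSH1 22 °C replicate 1, 22 °C replicate 2, 4 °C replicate 1 and 4 °C replicate 2.

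**Figure D2:**
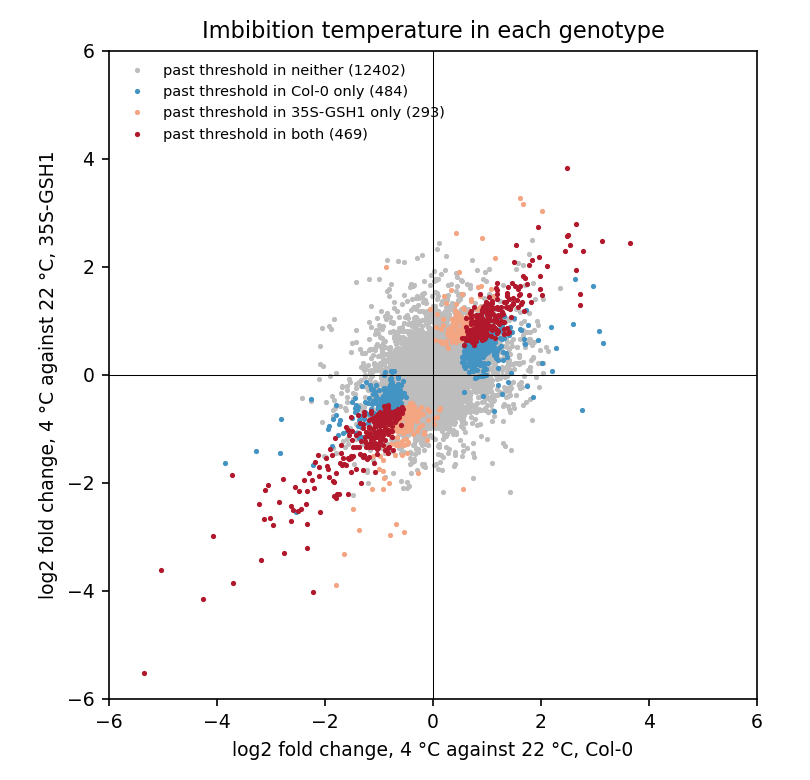
Log2 fold change at 4 °C against 22 °C in Col-0 (horizontal axis) and in 35S-GSH1 (vertical axis) for each of the 13648 probe sets tested, coloured by the genotypes in which limma placed the probe set past the adjusted p threshold of 0.05. The 469 probe sets past the threshold in both genotypes lie in the lower left (237) and the upper right (232) corners of the plot.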

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

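The mitochondrion-encoded genes were put together as a list only after the data were seen, so the test given here was chosen after the result. The temperature difference of the 16 mitochondrion-encoded genes tested differed between the genotypes by camera's test of the interaction: the median log2 change at 4 °C was -0.57 in Col-0 and -0.15 in 35S-GSH1, the median interaction was 0.47 with 15 of 16 genes above 0, and the adjusted p was 0.0169 over 156 tests. The adjusted p was 0.953 with an estimated correlation and 0.942 with fry, and with limma 0 of the 16 genes passed the threshold alone. The per-array mean of these genes had an SD of 0.74 log2 units in Col-0 at 4 °C (n = 2). This mean was lower in replicate 2 than in replicate 1 in all 4 groups, so part of that SD may be shared by arrays of the same number. No label ties the number to a batch. Within replicate 1 and replicate 2 the interaction of the per-array means was 0.26 and 0.63, and with the replicate number as a block camera gave an adjusted p of 2.7e-05 (p = 0.175 with an estimated correlation, not adjusted). The median change in Col-0 was -0.037 without Col-0 4 °C replicate 2 and -1.11 without Col-0 4 °C replicate 1, so the size of this change rested on single arrays.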

How the results depend on the processing

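All settings here were chosen before the data were examined except the pseudocount of 16, added because the planned pseudocount of 1 was also the main one. The alternatives for the GSH1 level were not run, since no probe set was paired with that gene. The causes of the changes below were not tested, apart from thresholds and smaller sets of arrays, which act by construction. For temperature in Col-0, temperature in 35S-GSH1 and their overlap, the counts were 153, 117 and 70 without the intensity trend, 1512, 1253 and 750 at an adjusted p of 0.10, and 408, 373 and 204 with an added minimum of 2-fold. Leaving out 1 array gave 427 to 852, 257 to 792 and 202 to 362. The genotype count at 22 °C was 2 with a pseudocount of 16 and 0 to 1 without 1 array, and at 4 °C it was 0 to 1 without 1 array; the interaction count was 0 throughout. Heat shock proteins lost their call with an estimated correlation in all 3 contrasts (adjusted p = 0.226 in each), and with fry for genotype at 4 °C (0.0707). Without 1 array their camera adjusted p ran from 0.00695 to 0.171 for genotype at 4 °C, from 0.00695 to 0.0214 for temperature in Col-0 and from 0.00695 to 0.0577 for temperature in 35S-GSH1. Of 52 values of named genes past the threshold, 28 passed under every setting in which they could be tested and 0 changed sign; 21 were not past it without the intensity trend and 15 without a filter, and at the 60th percentile filter only 23 could be tested. Of 28 named values not past the threshold, 16 stayed the same under every setting run; 9 passed with the replicate number as a block, 8 at an adjusted p of 0.10 and 3 at the 60th percentile filter, and 2 changed sign, in 3 settings: GR for genotype at 22 °C was -0.021 without Col-0 22 °C replicate 2 (-0.021 to 0.11 over the arrays), and GR1 for genotype at 4 °C was 0.094 and 0.0052 without Col-0 4 °C replicate 2 and 35S-GSH1 4 °C replicate 2 (-0.15 to 0.094). With the replicate number as a block, the counts were 1692, 1386 and 867 for temperature in Col-0, in 35S-GSH1 and their overlap and 1 for genotype at 22 °C, and the heat shock proteins had camera adjusted p-values of 0.00687, 0.00799 and 0.0107. The deviations of same-numbered arrays correlated at 0.0506 to 0.143 between groups. The main fit was planned without the replicate number, with the block as an alternative, and these correlations did not decide that choice. All of them were positive, and the labels do not say what the number stands for. Anything shared by arrays of the same number counts as spread in the main fit, which can hide calls. The low genotype counts are limited by this too.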

Other observations

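The lists of hypoxia-responsive and organelle-encoded genes, the gene families, the comparison averaged over both temperatures and the tests of organelle yield and of normalization were all chosen after the data were seen. Several of the largest named drops at 4 °C in Col-0 were in genes known to respond to low oxygen, namely AT4G33560, AT5G10040 and AT5G66985. Only AT4G33560 was also among the largest named drops in 35S-GSH1. A list of hypoxia-responsive genes was therefore written from general knowledge and tested without these 3 genes that prompted it. Of the 19 genes left, 10 were lower and 2 higher at 4 °C in Col-0, and 9 lower and 2 higher in 35S-GSH1, by the limma adjusted p. AT3G03270 had log2 fold changes of -2.34 (SE 0.24) and -2.40 (SE 0.24) in Col-0 and 35S-GSH1, AT2G17850 -1.87 and -1.48, and AT3G27220 -1.13 and -1.34. In the opposite direction, PDC2, a pyruvate decarboxylase of ethanol fermentation, rose by 0.98 and 0.83 (SE 0.16 for each), and AT4G10270 by 0.88 and 1.49.

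The 65 transcripts encoded in the plastid genome had a median log2 difference between 35S-GSH1 and Col-0 of -0.38 at 22 °C (49 of 65 below 0) and -0.40 at 4 °C (55 of 65). With limma 0 of the 65 passed the threshold at either temperature, where 779 and 439 of all probe sets had an unadjusted p under 0.05. Adjusted over the list alone, 16 were lower at 22 °C and 8 at 4 °C and 0 higher, which is not independent evidence, since the list was chosen on these data. Camera gave adjusted p-values of 1.41e-11 and 9.1e-16 for the list, but the adjusted p was 0.763 and 0.746 with an estimated correlation and 0.650 with fry at each temperature. The size rested on single Col-0 arrays: at 22 °C the median was -0.20 without Col-0 22 °C replicate 1 and -0.62 without replicate 2, and at 4 °C it was -0.11 without Col-0 4 °C replicate 1 and -0.66 without replicate 2. Averaged over the temperatures, limma placed 3 probe sets past the threshold and all 3 were plastid genes: clpP with -0.93 (SE 0.12, adjusted p = 0.0320), rps4 with -1.01 (SE 0.15, adjusted p = 0.0457) and atpE with -0.68 (SE 0.10, adjusted p = 0.0457). They encode a subunit of the plastid Clp protease, a plastid ribosomal protein and a subunit of the plastid ATP synthase. Among 22 °C samples the 7 genes of the TET family, which encode tetraspanins, had a median of -0.42 with 7 of 7 below 0 (camera adjusted p = 0.0428, 0.746 with an estimated correlation, 0.177 with fry), while at 4 °C the median was 0.15 with 2 of 7 below 0 (camera adjusted p = 0.873). With limma 0 of the 7 passed at either temperature, with a smallest adjusted p of 0.844, and camera gave an adjusted p of 0.0741 for the interaction, so the temperatures were not shown to differ. Among the probe sets higher in 35S-GSH1 over both temperatures, the smallest p was that of 254270_at, chosen here after its values were seen, whose gene is not listed in the table used. Its averaged log2 difference was 1.11 (SE 0.22, limma adjusted p = 0.249), and its normalized intensity was 2331 to 3251 on the 4 35S-GSH1 arrays and 771 to 1909 on the 4 Col-0 arrays. Whether it measures the overexpressed gene was not analysed here.

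For the hypoxia-responsive genes, the list median was -0.89 in Col-0 and -0.59 in 35S-GSH1, and camera's larger p of the 2 genotypes was 1.91e-06, a value consistent with lower expression of these genes after imbibition in the cold. This call was lost with an estimated correlation (adjusted p = 0.746 in Col-0 and 0.763 in 35S-GSH1) and with fry (adjusted p = 0.177 in each), so the correlation among the genes stays open. The list median was -0.53 or lower in both genotypes on the deposited scale, after quantile normalization and after median centring. The choice among these scalings therefore does not account for it. They moved the median of all genes by only 0.15 in Col-0 and 0.16 in 35S-GSH1. That is too little to have removed a median of this size, so other errors of normalization stay open. A trend with probe-set brightness is argued against by 0% of 10000 lists matched on mean expression having a median as low. The oxygen supply of the seeds was not measured in these data, so a role of oxygen remains a hypothesis.

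For the plastid-encoded genes, camera gave an adjusted p of 1.35e-21 for the averaged comparison, but the adjusted p was 0.746 with an estimated correlation and 0.427 with fry. A trend with probe-set brightness is argued against by 0% of 10000 matched lists reaching the median. Normalization stays open: the median was -0.39 or lower under 3 scalings, but these moved the median of all genes by only 0.014, too little to test it. Spread between arrays stays open too, as the per-array mean differed by -0.38 (95% interval -0.86 to 0.09), with an exact permutation p of 0.0556, the smallest that the 36 permutations of genotype within temperature can give. A lower yield of all organelle transcripts may also contribute and cannot be told apart from a change in the plastid alone or an effect of the genotype: the 16 mitochondrion-encoded genes had a median of -0.25 at 22 °C (15 of 16 below 0) but 0.18 at 4 °C (14 of 16 above 0), and the plastid mean minus the mitochondrial mean differed by -0.33 with an interval of -1.04 to 0.37.

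For the averaged genotype comparison, chance could not be excluded: of the 34 splits of the 8 arrays into 4 and 4 other than the one by temperature, 4 gave 3 or more calls, the real split with 3 among them, and the highest of the others gave 32. The remaining ones, with 3 and 4 calls, were unbalanced by temperature, unlike the real split and the one with 32 calls. Unbalanced splits were fitted with split and temperature as separate terms and balanced ones with a coefficient for each of 4 groups. Their counts are thus not from the same model. Among the other balanced splits only the one with 32 calls gave any. The split with 32 calls parted the arrays by replicate number. A structure of the samples that the labels do not name may lie behind it, but this was not tested. With the replicate number as a block the averaged count was 10, with 1 higher and 9 lower.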
